A study of Arabidopsis thaliana with 36 samples.

How the data were processed

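Per the labels, messenger RNA of rosette leaves, early flowers (stages 1 to 9) and late flowers (stages 10 to 12) was measured in wild type and in a bzip28 bzip60 double mutant, at 22 C and after 3 hours at 37 C, in 36 libraries. Per the labels' protocols, plants grew under 16 hours of light and 8 of dark, total RNA was extracted with Trizol, and cDNA libraries were sequenced on a HiSeq 3000. Per the submitters' processing notes, reads were aligned to TAIR10 with TopHat2 2.0.13 and counted with HTSeq, whose version, strand setting and annotation release are not given in the sources used here. The deposited table holds read counts per gene, in the unit count, per the file headers 1 column for each library. Its columns were checked to hold whole numbers, and each was matched to its sample by name.

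The table lists 32678 loci, of which 31912 matched the TAIR10.1 gene table used for names and positions and 28008 had any count. Library totals ran from 8.03 to 29.7 M. Genes were kept by filterByExpr with the 12 groups (minimum count 10, minimum total 15), leaving 22843. Libraries were scaled by TMM, and a quasi-likelihood model with a mean for each of the 12 groups was fitted with edgeR 4.0.16 in R 4.3.3 (24 residual degrees of freedom). Each of 21 contrasts was tested with an F test and adjusted with the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The standard error of a log2 fold change is its size over the square root of F. CPM means and SDs use TMM-scaled totals. For a group at 0 counts, a fold was computed against a floor of 3 counts over the group, and for a group with 1 to 3 counts the ratio of summed counts is given with its 95% counting interval.

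In all, 18 gene lists with 341 members were fixed before the data were examined, and 339 members were tested. HSFB1 had 0 counts in every library, and GEX2 did not pass the filter. Each list was tested with camera of limma 3.58.1 at a correlation of 0.01 on log2 CPM (prior count 2), adjusted over the lists within a contrast, and its members were also adjusted over the list alone. Beside each called camera value in the text stands that with an estimated correlation. Genes were named by a fixed rule: per contrast the 4 largest called rises and 4 largest falls with at least 10 CPM in the higher group, from each list up to 3 called rises, 3 called falls and 2 uncalled members, and BZIP28, BZIP60, BIP1, BIP2 and BIP3 always. The text names a selection of these, and a few other genes that it marks.

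Alternatives fixed beforehand were RLE size factors, the DESeq2 1.42.0 Wald test, no filter, a stricter filter (at least 1 CPM in 3 libraries and 100 counts in all), fits of the compared groups or of the tissue only, replicate number as a block in both the full and the compared-groups fit, removal of organelle-encoded genes, and each library left out in turn. Lists were also tested with camera at an estimated correlation, with fry, whose p-values depend on the order of groups in the design (here alphabetical), and with the block. Added after the data were seen were depth class as a term (boundary 17 M), all wild-type replicate 1 libraries left out, and limma voom with library weights.

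Chance was examined by regrouping libraries: all 10 splits for 3 against 3, and 100 splits of 200 for interactions, with the main effect of tissue or genotype as an offset. All of these tests were chosen after the results were seen. For interactions, free splits (60 of 200) were run first, then splits that mix tissues or genotypes alike (60 of 82), then those with the offset, and all are reported. For tissues the offset splits that part every pair are also given. The fit was tested on simulated data with 200 genes changed 2-, 4- or 8-fold: in wild-type late-flower heat it recovered 35.8, 86.6 and 95.5% of them, in the late-flower genotype by heat interaction 16.4, 71.6 and 81.8%, and in the early-flower against leaf interaction 2.99, 74.6 and 87.9%. Among unchanged genes 25, 29 and 11 were called, 14.7, 20.4 and 9.09% of all calls where the threshold sets 5%. Between genotypes at 37 C in late flowers 32.8, 86.6 and 93.9% were recovered and 22 calls (13.4%) were false.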

Results

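Messenger RNA was counted per gene in 36 sequencing libraries of Arabidopsis thaliana, accession Col-0, from plants held at 22 C or heated at 37 C for 3 hours. Both the wild type and a double mutant of BZIP28 and BZIP60 were sampled. These genes encode transcription factors of the unfolded protein response, which raises folding capacity in the endoplasmic reticulum (ER). From each plant type came rosette leaves, early flowers (stages 1 to 9) and late flowers (stages 10 to 12). That gives 12 groups with n = 3 libraries each. Titles mark the controls 0 h and the heated samples 3 h, so all heat changes below, as of clock genes, can include elapsed time. Total counts ran from 8.03 to 29.7 M per library. In 24 libraries they lay between 21.3 and 29.7 M, and in the other 12 between 8.03 and 13.5 M. The shallower 12 were replicate 1 of all 6 wild-type groups, all mutant leaf controls (12.1 to 13 M) and all heated mutant late flowers (11.3 to 13.5 M).

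Values below are log2 fold changes ± SE from edgeR's quasi-likelihood fit of all 36 libraries over 22843 genes, with Benjamini-Hochberg adjusted p, unless a unit is named. A gene is called, and said to rise or fall, where adjusted p is under 0.05. P-values use the spread between these samples, pooled over the 12 groups. Leaf replicates varied more than flower controls, so leaf p-values may be too small and flower ones too large. Labels state only triplicate collection. With no stated strand setting, overlapping genes and near-identical copies (as of HSP70, HSP90 and BIP) are less certain. Counts marked list alone adjust p over that list. Gene lists, contrasts, test and naming rule were chosen before the data were examined.

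The targeted genes came first. BZIP28 (AT3G10800, chromosome 3, bases 3379168 to 3381621 of TAIR10.1) had 28.6 to 175 CPM (counts scaled to library totals) in the 18 wild-type libraries. The 18 mutant ones had 12 to 40.3. BZIP60 (AT1G42990, chromosome 1, bases 16135723 to 16137463) had 20.2 to 260 CPM in wild type and 5.88 to 26.3 in the mutant. Within each tissue and temperature every mutant library lay below every wild-type library for both genes. At 22 C, leaf BZIP60 was 206 ± 48.2 CPM (mean ± SD) in wild type and 21.1 ± 5.73 in the mutant, and leaf BZIP28 was 93.2 ± 20.6 and 23.4 ± 0.673. BIP3 (AT1G09080, chromosome 1, bases 2929217 to 2931850), an ER chaperone gene, had 0 counts in all mutant leaf and early-flower libraries. Wild-type early flowers had only 2 to 25.

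**Figure D1:**
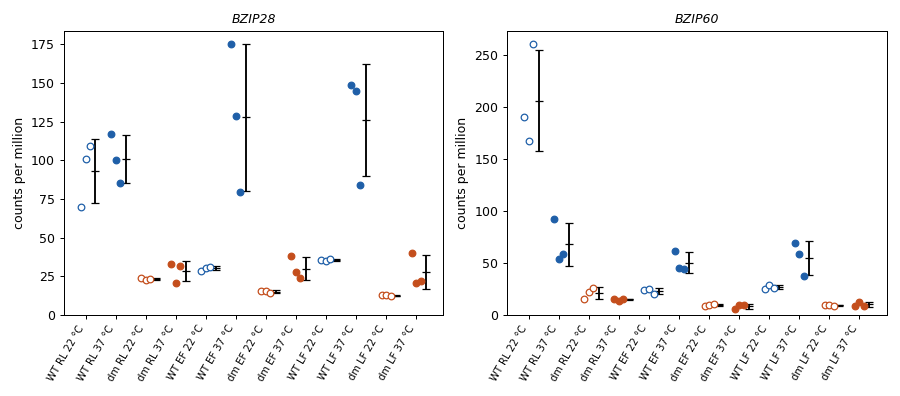
CPM (vertical axis) of BZIP28 and BZIP60 in each of the 36 libraries (points, open at 22 C and filled at 37 C, wild type in blue and double mutant in orange), with group mean ± SD in black, n = 3.

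The first comparison was of heat in wild-type leaves. Small heat shock proteins, which hold unfolding proteins in solution, rose strongly: plastid HSP21 by 10.73 ± 1.45 and cytosolic HSP18.2 by 10.30 ± 1.43 (n = 3 per group). Peroxidase gene APX2 rose by 9.35 ± 0.93. Genes of salicylate defence fell, among them the synthesis gene ICS1 (-4.83 ± 0.96) and the exporter gene EDS5 (-4.56 ± 1.03). BZIP60 fell (-1.60 ± 0.24) and BZIP28 was not called (0.11 ± 0.25). In all, 3364 genes rose and 3991 fell (3675 and 3316 without a filter), of which 1831 and 2795 changed at least 2-fold.

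Of the small heat shock proteins, 14 of 16 rose (15 rose list alone), with camera adjusted p = 1.2e-12, adjusted p = 0.23 with an estimated correlation. Of the larger cytosolic and organellar heat shock proteins, 7 rose and 2 fell of 23 (7 rose and 3 fell list alone): HSA32 rose by 6.54 ± 0.87 and HSP70T-2 by 5.63 ± 0.85, and HSC70-2 fell (-3.91 ± 1.07). The list gave camera adjusted p = 0.076. Heat shock factors and co-regulators had 7 rises and 1 fall of 24, list alone the same (camera adjusted p = 0.12). DREB2C rose by 4.21 ± 0.75 and DREB2B by 3.82 ± 0.41. HSFA2, which prolongs the response, was not called (-0.08 ± 1.21). It had 22.7, 316 and 350 CPM in controls and 87, 476 and 89 after heat. ER folding had 2 rises and 4 falls of 25, list alone the same (camera adjusted p = 0.77). The disulfide-forming oxidase ERO1 (-2.66 ± 0.62), BIP3 (-1.53 ± 0.51) and the calreticulin CRT3 (-1.44 ± 0.51) fell. PDIL2-3 (1.19 ± 0.29) and CRT1A (1.04 ± 0.29) rose. The list of ER-associated degradation (ERAD), glycosylation and export had 3 rises and 1 fall of 18, list alone the same, among them DER2.1 (0.75 ± 0.23), with camera adjusted p = 0.31. Of a list of 10 further regulators of the unfolded protein response, without BZIP28 and BZIP60, only NAC062 changed (-1.23 ± 0.37; camera adjusted p = 0.56).

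The salicylate and defence list had 15 falls of 17, list alone the same, with camera adjusted p = 2e-07, adjusted p = 0.4 with an estimated correlation. Among clock genes 9 rose and 2 fell of 13 (list alone the same), led by the evening gene PRR5 (3.70 ± 0.53) and the morning gene LHY (-4.23 ± 1.00), with camera adjusted p = 0.0012, adjusted p = 0.23 with an estimated correlation. Clock time is not given. Dehydration genes of the abscisic acid list rose in 5 of 17 cases, including KIN1 (3.60 ± 0.59) and GOLS1 (2.64 ± 0.56), with camera adjusted p = 0.12. Other lists were reactive oxygen scavenging 5 rises and 2 falls of 18, list alone the same (camera adjusted p = 0.21), jasmonate 3 falls of 17, list alone 2 (camera adjusted p = 0.42), and photosynthesis 4 falls of 23, list alone the same (camera adjusted p = 0.079), the last led by LHCB1.3 (-2.48 ± 0.63). Reference genes had 1 rise and 1 fall of 8, list alone the same (camera adjusted p = 0.41). Flower lists are bud markers here: floral organ identity 3 rises of 16, list alone 0 (camera adjusted p = 0.079), tapetum and pollen wall 3 rises of 24, list alone 0 (camera adjusted p = 0.17), meiosis 1 rise and 1 fall of 9, list alone the same (camera adjusted p = 0.56), late pollen and sperm 4 rises of 31, list alone 2 (camera adjusted p = 0.076) and cell cycle 4 rises and 1 fall of 30, list alone 1 and 1 (camera adjusted p = 0.34). Other well-expressed genes were AT3G30843 (0 counts at 22 C, at least 257-fold higher) and PP2-A5, which fell 974-fold (95% counting interval 269 to 8050). A fit of the leaf libraries only called 3672 genes, one of the compared groups only 4896, and that with a replicate block 4541, against 7355. Groups did not overlap for 6522 of the called genes, where chance gives 10% of genes here and in every later pair of groups, and for 38.4% of all genes. BIP3 lost its call without control 1 (-1.39), 3 (-1.09), heated 1 (-1.59) or 2 (-1.12), and CRT1A without heated 3 (0.51). CRT3 lost its call without control 2 (-1.47), 3 (-1.12), heated 1 (-1.47) or 2 (-1.07). DER2.1 lost its call without control 2 (0.68), 3 (0.69) or heated 2 (0.63).

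Wild-type early flowers came next. The factor gene HSFA7B rose 1420-fold (95% counting interval 392 to 11700) (n = 3 per group), mitochondrial HSP23.6 by 10.64 ± 1.62 and cytosolic HSP70B by 8.61 ± 1.60. Both targeted factors rose, BZIP28 by 2.09 ± 0.26 and BZIP60 by 1.12 ± 0.24, together with the ER folding list genes ERDJ3A (3.49 ± 0.51), TIN1 (3.40 ± 0.50) and BIP3 (2.53 ± 0.88). Cell division genes fell, such as KNOLLE (-1.54 ± 0.45) and AUR1 (-1.84 ± 0.48). In all, 3713 genes rose and 4631 fell (4776 and 4387 in a fit of the compared groups), 2069 and 3136 of them at least 2-fold.

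Small heat shock proteins had 15 rises of 16, list alone the same (camera adjusted p = 7.4e-18, adjusted p = 0.05 with an estimated correlation) and the larger ones 17 rises and 0 falls of 23, list alone 18 and 1 (camera adjusted p = 4.6e-11, adjusted p = 0.24 with an estimated correlation), among them ROF2 (7.19 ± 0.80) and HSP70-4 (7.27 ± 1.09). Of heat shock factors and co-regulators 15 of 24 rose (list alone the same), with camera adjusted p = 3.3e-09, adjusted p = 0.026 with an estimated correlation. ER folding had 7 rises and 2 falls of 25, list alone the same (camera adjusted p = 0.13), with PDIL1-4 at -0.79 ± 0.18 and BIP1 not called (0.95 ± 0.54). The ERAD list had 11 rises and 1 fall of 18, list alone the same (camera adjusted p = 5.7e-05, adjusted p = 0.12 with an estimated correlation), including the ubiquitin ligase partner HRD3A (1.91 ± 0.24) and DER2.1 (1.66 ± 0.24). Among regulators of the unfolded protein response, NAC089 (2.14 ± 0.35), BZIP17 (1.14 ± 0.26) and IRE1A (0.96 ± 0.22) rose and BAG7 (-1.24 ± 0.22) and IRE1B (-0.63 ± 0.22) fell (camera adjusted p = 0.41).

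Dehydration genes had 15 rises of 17, list alone 16 (camera adjusted p = 4.6e-11, adjusted p = 0.051 with an estimated correlation), with RAB18 up 8.34 ± 1.44 and GOLS1 up 5.63 ± 0.64. Clock genes had 10 rises and 2 falls of 13, list alone 11 and 2 (camera adjusted p = 1e-06, adjusted p = 0.027 with an estimated correlation), and oxygen scavengers 5 rises and 1 fall of 18, list alone the same (camera adjusted p = 0.044, adjusted p = 0.34 with an estimated correlation). Cell cycle genes had 22 falls of 30, list alone 29 (camera adjusted p = 1.5e-05, adjusted p = 0.59 with an estimated correlation). Meiotic genes had 1 rise and 4 falls of 9, list alone 1 and 5 (camera adjusted p = 0.34): the recombinase gene DMC1 fell (-1.56 ± 0.35) and ASY1, of the chromosome axis, rose (2.74 ± 0.63). In the tapetum list GRP17, a pollen coat protein gene, fell (-6.01 ± 1.40) and TKPR1 rose (1.52 ± 0.47), with camera adjusted p = 0.91. Of floral identity genes only CRC fell (-1.99 ± 0.60) and only SEP4 rose (1.21 ± 0.33; camera adjusted p = 0.84). Among well-expressed genes the largest falls included XTH3 (-8.00 ± 1.78) and SHT (-7.73 ± 1.47), the latter a spermidine acyltransferase gene of the tapetum. Control 2 stood apart here: controls 1 to 3 had 0.248, 89.5 and 0.891 CPM of XTH3, 2.86, 51 and 0.271 of SHT and 4.53, 264 and 5.74 of GRP17. SHT was at -4.11 without control 2. Without the shallower wild-type replicate 1 libraries, a setting added after the data were seen, 5328 genes were called against 8344, and limma voom with library weights called 13154. No overlap between groups was seen for 7889 called genes and 51.6% of all. BIP3 lost its call without control 1 (2.41), 3 (2.16) or heated 1 (1.58), and GRP17 without control 2 (-1.91). IRE1B lost its call without control 2 (-0.62), 3 (-0.54), heated 1 (-0.53) or 2 (-0.59), and SEP4 without heated 3 (0.87). TKPR1 lost its call without control 2 (1.42) or heated 1 (1.31), and XTH3 without control 2 (-2.40). Oxygen scavenging lost the camera call without control 1 (adjusted p = 0.076) or heated 3 (0.061).

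Wild-type late flowers followed. HSFA7B rose 1000-fold (95% counting interval 276 to 8260) (n = 3 per group), the ER small heat shock protein gene HSP22.0 by 10.26 ± 1.65, HSP90.1 by 7.73 ± 1.17 and the co-chaperone gene HOP3 by 7.31 ± 0.93. BZIP28 (1.82 ± 0.26), BZIP60 (1.05 ± 0.24), BIP3 (3.34 ± 0.63) and the ERAD gene DER1 (2.13 ± 0.23) rose. The cell wall invertase gene CWINV2 fell (-4.36 ± 0.66), as did the pollen sugar transporter gene STP9 (-2.36 ± 0.63). In all, 3653 genes rose and 2271 fell, 1750 and 1632 of them at least 2-fold. That 61.7% share of rises depended on scaling: with median-of-ratios (RLE) size factors 2849 rose and 3138 fell (47.6%), without a filter 2455 and 3071, and the median of all genes moved by -0.13 log2.

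Among small heat shock proteins there were 15 rises of 16, list alone the same (camera adjusted p = 1.5e-19, adjusted p = 0.055 with an estimated correlation), the larger ones 18 rises of 23, list alone the same (camera adjusted p = 9.2e-12, adjusted p = 0.25 with an estimated correlation) and heat shock factors 12 rises of 24, list alone 13 (camera adjusted p = 2.8e-07, adjusted p = 0.055 with an estimated correlation). ER folding had 7 rises and 1 fall of 25, list alone the same (camera adjusted p = 0.065): TIN1 (2.46 ± 0.48) and ERDJ3A (2.42 ± 0.48) rose and PDIL1-4 fell (-0.64 ± 0.17). The ERAD list had 8 rises and 1 fall of 18, list alone 9 and 1 (camera adjusted p = 0.00032, adjusted p = 0.22 with an estimated correlation), and dehydration genes 7 rises of 17, list alone the same (camera adjusted p = 0.0013, adjusted p = 0.49 with an estimated correlation), led by GOLS1 (4.85 ± 0.62). Clock genes had 9 rises and 2 falls of 13, list alone the same (camera adjusted p = 0.00032, adjusted p = 0.12 with an estimated correlation), PRR5 rising by 3.96 ± 0.53. Cell cycle genes had 16 falls of 30, list alone 20 (camera adjusted p = 3.3e-07, adjusted p = 0.49 with an estimated correlation), such as KNOLLE (-1.69 ± 0.46). No tapetum gene was called (camera adjusted p = 0.02, adjusted p = 0.58 with an estimated correlation), and among floral identity genes only SPL, a sporogenesis regulator, fell (-1.35 ± 0.44). Without the wild-type replicate 1 libraries 2737 genes were called against 5924, while fits of the tissue only, of the compared groups with a replicate block and with voom weights called 9672, 9240 and 11173. The 2 groups were apart for 5800 called genes and 52.3% of all. SPL lost its call without heated 1 (-1.11) or 2 (-1.42). Tapetum lost the camera call without control 1 (adjusted p = 0.068), 3 (0.12) or heated 2 (0.11).

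Across tissues of the wild type, 1422 genes rose in all 3 where independent lists would share 87, and 757 fell in all 3 where 80 would. Without the wild-type replicate 1 libraries these counts were 764 and 187. GOLS1 and ASY1 were among the shared rises, with 2.64 and 4.04 in leaves, 5.63 and 2.74 in early flowers and 4.85 and 2.62 in late flowers. RVE8, a clock activator, was among the shared falls (-1.25, -1.87 and -1.72). Heat strength varied within groups: HSP101, a disaggregase gene, had 6050, 3740 and 355 CPM in wild-type heated early flowers and 2430, 5460 and 620 in heated late flowers. In leaves it had 428, 958 and 400 CPM after heat and 88.8, 325 and 263 at 22 C, and in mutant leaves 591, 126 and 987 after heat and 39.7, 107 and 69.6 at 22 C.

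**Figure D2:**
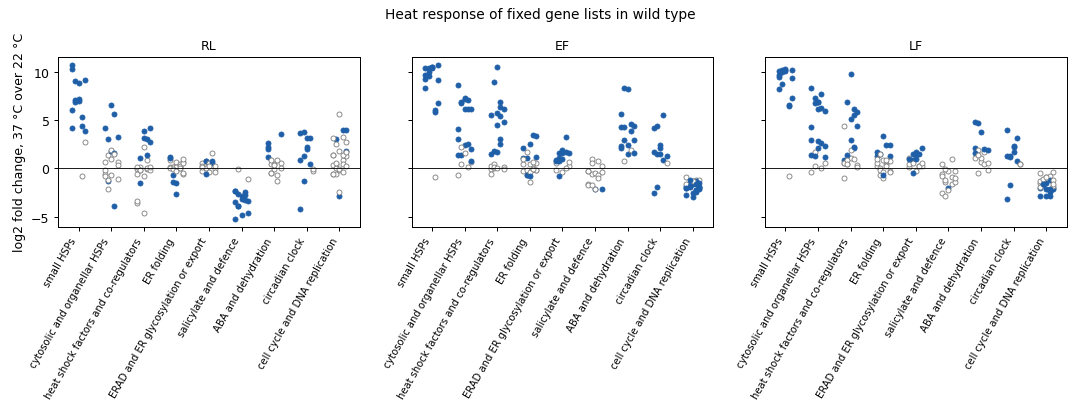
Log2 fold change of 37 C over 22 C in wild type for each member (point) of 9 fixed lists, in rosette leaf (RL), early flower (EF) and late flower (LF), with filled points for called genes. Small heat shock protein medians were 6.92, 9.58 and 9.57.

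In heated mutant leaves HSP21 rose by 8.05 ± 1.26 (n = 3 per group), HSP17.4 by 6.34 ± 1.25 and APX2 by 5.43 ± 0.68. TIN1 (3.25 ± 0.50) and ERDJ3A (2.79 ± 0.51) rose, while BIP3 had no counts. ICS1 (-5.74 ± 1.00), the defence gene PAD4 (-4.70 ± 0.80) and the lipoxygenase gene LOX4 (-5.59 ± 0.94) fell, and jasmonate genes had 1 rise and 8 falls of 17, list alone the same (camera adjusted p = 0.024, adjusted p = 0.82 with an estimated correlation). Flower identity genes STK (4.55 ± 1.54), AP1 (3.61 ± 1.15) and AP3 (2.99 ± 1.01) also rose. These rises moved with 1 library: the floral list summed to 237 CPM in heated mutant leaf replicate 2 and to between 24.2 and 88.7 in the other 11 leaf libraries. In all, 2949 genes rose and 3673 fell, against 3445 and 2945 without a filter and 3351 and 3298 with the stricter one. AP1 lost its call without control 1 (3.49), 3 (3.05) or heated 2 (-2.71). AP3 lost its call without control 1 (2.88) or 3 (2.74) and was called as a fall without heated 2 (-3.65). STK lost its call without control 2 (3.94), 3 (4.00) or heated 2 (-4.62). Jasmonate lost the camera call without control 1 (adjusted p = 0.25) or heated 1 (0.12).

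Small HSP genes had 14 rises of 16, list alone 15 (camera adjusted p = 3.6e-11, adjusted p = 0.35 with an estimated correlation), the larger ones 13 rises and 1 fall of 23, list alone 13 and 2 (camera adjusted p = 0.0013, adjusted p = 0.82 with an estimated correlation) and heat shock factors 5 rises and 1 fall of 24, list alone the same (camera adjusted p = 0.092). ER folding had 3 rises and 2 falls of 25, list alone the same (camera adjusted p = 0.29) and the ERAD list 5 rises and 1 fall of 18, list alone 5 and 2 (camera adjusted p = 0.12). Salicylate genes had 15 falls of 17, list alone the same (camera adjusted p = 4.8e-05, adjusted p = 0.78 with an estimated correlation). Clock genes had 7 rises and 2 falls of 13, list alone 7 and 3 (camera adjusted p = 0.0031, adjusted p = 0.35 with an estimated correlation). Of these libraries all controls were shallow and all heated ones deep. With depth class as a term, which only wild-type replicate 1 libraries inform, 6348 genes were called against 6622. Fits of the compared groups only, of those with a replicate block and of the tissue only called 402, 1080 and 3214 genes against 6622. Libraries of the groups stayed apart for 4628 called genes and 25.6% of all.

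In mutant early flowers APX2 rose by 9.59 ± 0.80 (n = 3 per group), HSP22.0 by 8.77 ± 1.55, HSFA7B by 7.20 ± 1.05 and the dehydration gene RAB18 by 8.71 ± 1.49. TIN1 (4.54 ± 0.53), ERDJ3A (4.23 ± 0.52) and the ERAD gene DER2.1 (1.56 ± 0.23) rose and CRT1A fell (-0.95 ± 0.29). The remaining BZIP28 transcript rose by 0.99 ± 0.26 and BZIP60 was not called (-0.19 ± 0.24). In all, 3561 genes rose and 4052 fell (4254 and 3855 in such a fit). Small heat shock proteins had 15 rises of 16, list alone the same (camera adjusted p = 5.8e-17, adjusted p = 0.045 with an estimated correlation), heat shock factors 15 rises of 24, list alone the same (camera adjusted p = 1.6e-09, adjusted p = 0.019 with an estimated correlation), dehydration genes 16 rises of 17, list alone the same (camera adjusted p = 3.5e-12, adjusted p = 0.045 with an estimated correlation) and clock genes 10 rises and 1 fall of 13, list alone 11 and 2 (camera adjusted p = 3e-07, adjusted p = 0.019 with an estimated correlation). ER folding had 3 rises and 3 falls of 25, list alone 2 and 2 (camera adjusted p = 0.84), the ERAD list 9 rises and 1 fall of 18, list alone 9 and 2 (camera adjusted p = 0.0026, adjusted p = 0.28 with an estimated correlation) and the cell cycle list 15 falls of 30, list alone 22 (camera adjusted p = 3e-06, adjusted p = 0.52 with an estimated correlation). HSP101 had 14900, 1970 and 1060 CPM in the heated replicates. Limma voom with library weights called 14859 genes against 7613. Complete separation was seen for 7140 called genes and 51% of all. CRT1A lost its call without heated 3 (-0.86).

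In mutant late flowers HSP21 rose by 13.56 ± 1.65 (n = 3 per group), HSP17.4 by 12.27 ± 1.60 and APX2 5360-fold (95% counting interval 1830 to 26000), and HSFA7B, with 0 counts at 22 C, was at least 2110-fold higher. ERDJ3A (3.05 ± 0.49), TIN1 (2.78 ± 0.48) and DER1 (1.60 ± 0.23) rose. The protein disulfide isomerase gene PDIL2-1 (-0.97 ± 0.29) and the glycoprotein folding sensor gene UGGT (-0.67 ± 0.19) fell. Remaining BZIP28 transcript rose by 1.13 ± 0.26. Heated replicate 1 stood apart in HSP101 (15100, 1210 and 1150 CPM). In all, 3167 genes rose and 1877 fell, a share of rises of 62.8% that was 53.3% with RLE size factors and 46.3% without a filter. Among small heat shock proteins there were 15 rises of 16, list alone the same (camera adjusted p = 5.7e-25, adjusted p = 0.021 with an estimated correlation), heat shock factors 14 rises of 24, list alone 15 (camera adjusted p = 5.2e-09, adjusted p = 0.021 with an estimated correlation), ER folding 2 rises and 3 falls of 25, list alone the same (camera adjusted p = 0.43), the ERAD list 6 rises and 1 fall of 18, list alone the same (camera adjusted p = 0.036, adjusted p = 0.55 with an estimated correlation) and cell cycle genes 9 falls of 30, list alone 10 (camera adjusted p = 8.9e-06, adjusted p = 0.55 with an estimated correlation). All heated libraries were shallow and all controls deep, and with depth class as a term 4039 genes were called. Fits of the tissue only, of the compared groups only and with voom weights called 8807, 8081 and 10581 genes against 5044, and 3060 were called without heated replicate 2. CPM ranges did not overlap for 4957 called genes and 52.3% of all. PDIL2-1 lost its call without heated 1 (-0.83). ERAD lost the camera call without control 1 (adjusted p = 0.058), 2 (0.058), heated 1 (0.08) or 2 (0.077).

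Mutant and wild type were then compared at each temperature, to see which transcripts differ between them. In leaves at 22 C, BZIP60 (-3.29 ± 0.26) and BZIP28 (-2.00 ± 0.26) were lower in the mutant, as were the ER folding list genes ERDJ3A (-3.19 ± 0.52) and TIN1 (-2.72 ± 0.49) (n = 3 per group). BIP3 went from 121 ± 76.9 CPM (SD) to 0 counts, at least 1150-fold lower. EARLI1, a lipid transfer protein gene, was higher (6.24 ± 0.93), with AT2G38870 (2.76 ± 0.35) and AT4G01980 (2.38 ± 0.36). In all, 10 genes were higher and 8 lower. In the ER folding list 3 of 25 were lower (9 lower list alone), with median -0.84 and camera adjusted p = 5.7e-24, adjusted p = 0.097 with an estimated correlation. Small HSP genes had 0 higher and 0 lower of 16, list alone 6 and 0 (camera adjusted p = 0.015, adjusted p = 0.78 with an estimated correlation), which moved with mutant control 2 (median 5.59 log2 CPM against 2.67 and 0.894 in the others), and the ERAD list 0 higher and 0 lower of 18, list alone the same (camera adjusted p = 0.0026, adjusted p = 0.46 with an estimated correlation). The cell cycle list (camera adjusted p = 3.4e-08, adjusted p = 0.46 with an estimated correlation) and the floral list (camera adjusted p = 0.00011, adjusted p = 0.46 with an estimated correlation) had no called member. Salicylate genes tested Down though their median was 0.38 (camera adjusted p = 0.015, adjusted p = 0.78 with an estimated correlation). MIR838 (-3.52 ± 0.45), also lower, was chosen after its values were seen. All mutant controls were shallow, so depth differs with genotype here. The count of 18 was 115 with DESeq2 (84 higher), 440 (121) with depth class as a term, 18 (5) with a replicate block, 13 (4) without wild-type replicate 1 libraries and 0 in a fit of the compared groups only, and without mutant replicates 1, 2 and 3 in turn it was 138 (129), 80 (64) and 45 (30). Groups did not overlap for 14 of the 18 and for 5.99% of all genes. EARLI1 lost its call without wild-type control 2 (5.94) or 3 (5.72), and TIN1 without wild-type control 3 (-2.40). ERAD lost the camera call without wild-type control 3 (adjusted p = 0.12) or mutant control 1 (0.69). Salicylate lost the camera call without wild-type control 3 (adjusted p = 0.2), mutant control 1 (0.23) or 2 (0.06). The small HSP list lost the camera call without wild-type control 3 (adjusted p = 0.48), mutant control 1 (0.072) or 2 (0.72).

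Early flowers at 22 C had higher QQS (4.29 ± 0.49), a starch regulator gene, and lower BZIP60 (-1.28 ± 0.24), EB1B (-2.21 ± 0.41), a microtubule plus-end gene, and the tapetum genes ATA7 (-6.30 ± 1.27) and TSM1 (-6.44 ± 1.37) in the mutant (n = 3 per group). BZIP28 was not called (-0.99 ± 0.26, adjusted p = 0.144). Wild-type control 2 stood apart in the 2 tapetum genes, with TSM1 at 7.82, 81.3 and 1.01 and ATA7 at 13.5, 33.3 and 0.853 CPM in controls 1, 2 and 3, but the tapetum list sum was highest in mutant control 1 (636, 187 and 175 against 305, 478 and 211 CPM in wild type). In all, 3 genes were higher and 26 lower. ER folding had 0 higher and 0 lower of 25, list alone the same (median 0.03; camera adjusted p = 0.4). The tapetum list had 1 lower of 24, list alone 3 (camera adjusted p = 0.17) and late pollen and sperm 0 higher and 0 lower of 31, list alone 0 and 3 (camera adjusted p = 0.048, adjusted p = 0.93 with an estimated correlation). The count of 29 was 108 with DESeq2, 6 in a fit of the compared groups and 56 with a replicate block. It was 2 (2 higher), 5 (3) and 3 (2) without mutant replicates 1, 2 and 3 and 77, 10 and 96 without those of the wild type. No overlap between groups was seen for 20 of the 29 and for 11.2% of all genes. ATA7 lost its call without wild-type control 2 (-5.09), mutant control 1 (-5.82), 2 (-7.07) or 3 (-6.15). BZIP60 lost its call without wild-type control 2 (-1.20), mutant control 1 (-1.16), 2 (-1.27) or 3 (-1.29). EB1B lost its call without wild-type control 2 (-2.09), mutant control 1 (-2.07), 2 (-2.25) or 3 (-2.19). TSM1 lost its call without wild-type control 2 (-3.60), mutant control 1 (-5.80), 2 (-7.80) or 3 (-6.25). Late pollen and sperm lost the camera call without wild-type control 2 (adjusted p = 0.29) or mutant control 1 (0.63).

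Late flowers at 22 C had 2 higher genes, AT4G01980 (4.03 ± 0.43) and QQS (3.23 ± 0.45), and 4 lower ones, BZIP60 (-1.53 ± 0.24), BZIP28 (-1.50 ± 0.26), EB1B (-2.48 ± 0.41) and AT1G03440 (-2.91 ± 0.46) (n = 3 per group). AT4G01980 was chosen here after its values were seen. ER folding had 0 higher and 0 lower of 25, list alone 0 and 1, the 1 being BIP3 (median -0.13; camera adjusted p = 0.003, adjusted p = 0.92 with an estimated correlation). Small heat shock proteins had 0 higher and 0 lower of 16, list alone the same (camera adjusted p = 0.016, adjusted p = 0.92 with an estimated correlation). The count of 6 was 21 with DESeq2, 19 with a replicate block and 190 with voom weights, and it was 2 (2 higher) without any 1 of the mutant replicates and 10 without wild-type replicate 2. The 2 groups were apart for all 6 and for 16.9% of all genes. AT1G03440 lost its call without mutant control 1 (-3.05), 2 (-2.89) or 3 (-2.78). BZIP28 lost its call without mutant control 1 (-1.50), 2 (-1.51) or 3 (-1.46). BZIP60 lost its call without mutant control 1 (-1.51), 2 (-1.54) or 3 (-1.50). EB1B lost its call without mutant control 1 (-2.46), 2 (-2.45) or 3 (-2.50). The small HSP list lost the camera call without wild-type control 1 (adjusted p = 0.12), 3 (0.54) or mutant control 3 (0.066).

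After heat, leaves of the mutant again had less BZIP60 (-2.19 ± 0.24) and BZIP28 (-1.83 ± 0.26), less of the calreticulin transcript CRT1A (-1.54 ± 0.29) and no BIP3 counts, at least 847-fold below wild type (n = 3 per group). EARLI1 (5.14 ± 0.79), AT2G38870 (3.23 ± 0.34) and AT4G01980 (2.75 ± 0.35) were higher, and the pollen regulator gene AGL104 lower (-3.07 ± 0.62). In all, 7 genes were higher and 9 lower. Of ER folding genes 2 of 25 were lower (9 lower list alone), with median -0.74 and camera adjusted p = 5.5e-15, adjusted p = 0.44 with an estimated correlation. It was 1 of 4 called lists here, none of them called with the estimate. By list-alone adjustment floral identity genes had 7 higher and 2 lower of 16, which moved with replicate 2 (237 summed CPM; camera adjusted p = 0.46). HEI10 (-3.15 ± 0.52), a crossover gene and also lower, was chosen after its values were seen. The count of 16 was 114 with DESeq2 (68 higher) and 0 in a fit of the compared groups only. It was 57 (44), 69 (22) and 224 (202) without mutant replicates 1, 2 and 3, and 8 (3) and 102 (44) without wild-type replicates 1 and 3. Libraries of the groups stayed apart for 14 of the 16 and for 5.92% of all genes. AGL104 lost its call without wild-type heated 1 (-3.14), 2 (-2.37) or mutant heated 2 (-2.93). CRT1A lost its call without wild-type heated 1 (-1.61), 3 (-1.01) or mutant heated 1 (-1.50), and EARLI1 without wild-type heated 1 (5.09) or 2 (5.85).

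Heated early flowers differed in 4 genes: AT4G01980 (6.48 ± 0.46) and QQS (4.73 ± 0.50) were higher and BZIP60 (-2.59 ± 0.25) and BZIP28 (-2.10 ± 0.26) lower in the mutant (n = 3 per group). ER folding had 0 higher and 0 lower of 25, list alone 0 and 1, the 1 being BIP3 (median -0.52; camera adjusted p = 4.6e-11, adjusted p = 0.51 with an estimated correlation), and the ERAD list had 0 higher and 0 lower of 18, list alone the same (camera adjusted p = 0.0015, adjusted p = 0.51 with an estimated correlation). BIP1 (-0.48 ± 0.54), BIP2 (-1.06 ± 0.69) and SHD, the ER form of HSP90 (-0.83 ± 0.40), were not called. The count of 4 was 33 with DESeq2 (4 higher), 19 (2) with a replicate block, 1858 with voom weights and 0 in a fit of the compared groups. Complete separation was seen for all 4 and for 5.22% of all genes. ERAD lost the camera call without wild-type heated 3 (adjusted p = 0.092) or mutant heated 1 (0.17).

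Heated late flowers had higher AT4G01980 (3.88 ± 0.38) and QQS (2.97 ± 0.44) and lower BIP3 (-6.30 ± 0.89), EB1B (-2.85 ± 0.43), BZIP60 (-2.43 ± 0.25), BZIP28 (-2.19 ± 0.27) and MIR838 (-2.79 ± 0.45) in the mutant (n = 3 per group). These are all 7 calls, and MIR838 was chosen after its values were seen. ER folding had 1 lower of 25, list alone 9 (median -0.91; camera adjusted p = 6.2e-26, adjusted p = 0.072 with an estimated correlation), the list-alone calls including CRT1B (-1.40 ± 0.39), UGGT (-0.78 ± 0.19) and SHD (-1.23 ± 0.41). The ERAD list had 0 higher and 0 lower of 18, list alone 0 and 1 (camera adjusted p = 1.3e-05, adjusted p = 0.15 with an estimated correlation). Mutant libraries were all shallow. The count of 7 was 23 with DESeq2, 114 with voom weights, 437 (406 lower) with depth class as a term and 3 in a fit of the compared groups. CPM ranges did not overlap for all 7 and for 7.48% of all genes. BIP3 lost its call without mutant heated 1 (-6.24) or 3 (-5.98), and MIR838 without mutant heated 1 (-2.58) or 2 (-2.81).

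**Figure D3:**
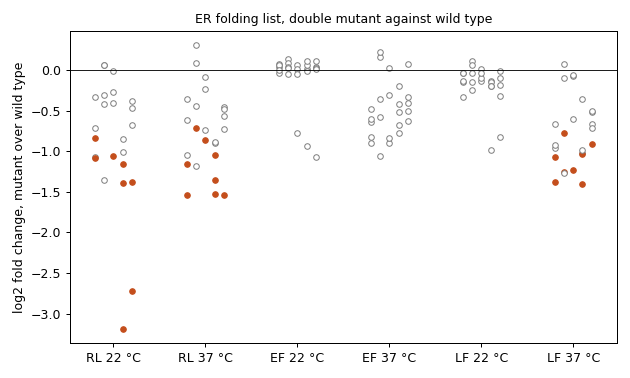
Log2 fold change of double mutant over wild type for the ER folding genes other than BIP3 in each tissue and temperature, filled where called with adjustment over the list alone.

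The genotype by heat interaction tested whether heat responses differ between genotypes. Only MIR838, chosen after its values were seen, was called, in leaves (3.55 ± 0.56, adjusted p = 0.0097), with 0 genes in early and 0 in late flowers by edgeR. Unadjusted p was under 0.05 for 831, 211 and 167 genes, each below the 5% chance gives. DESeq2 called 25, 12 and 3. BZIP60 responded by 1.09 ± 0.33, -1.31 ± 0.33 and -0.91 ± 0.34 relative to wild type in leaves, early and late flowers, and BZIP28 by 0.17 ± 0.36, -1.10 ± 0.36 and -0.69 ± 0.36, none of them called. The ER folding list had medians of -0.01, -0.62 and -0.66, the last 2 with camera adjusted p = 6e-08, adjusted p = 0.85 with an estimated correlation and camera adjusted p = 4.3e-13, adjusted p = 0.31 with an estimated correlation. In leaves its test was Up though its median was below 0 (camera adjusted p = 0.04, adjusted p = 0.79 with an estimated correlation), as for salicylate genes (median -0.09; camera adjusted p = 0.0059, adjusted p = 0.79 with an estimated correlation). Small heat shock proteins gave medians of -1.83 (camera adjusted p = 0.0044, adjusted p = 0.79 with an estimated correlation), -1.54 (camera adjusted p = 0.0013, adjusted p = 0.99 with an estimated correlation) and 1.39 (camera adjusted p = 0.00078, adjusted p = 0.87 with an estimated correlation). In leaves, early and late flowers camera called 9, 4 and 7 of the 18 lists, none of them with the estimate. Genes induced at least 2-fold in wild type numbered 1831, 2069 and 1750, and 0 of them in any tissue had a called lower or higher induction in the mutant by edgeR. Without heated mutant leaf replicate 2, which stood apart in HSP101 (126 CPM), 20 leaf genes had a called lower and 0 a called higher induction. Selection by the wild-type rise itself favours lower ones. Unadjusted p under 0.05 gave 127, 20 and 14 lower ones and 3, 38 and 1 higher ones (154 and 8 in leaves without that library), and DESeq2 called 12, 2 and 1 lower. Over left-out libraries the lower ones ran from 86 to 238 (without heated mutant replicate 1) in leaves, 12 (heated wild type 1) to 46 (heated wild type 3) in early and 8 (wild-type control 1 or heated 1) to 33 (heated mutant 1) in late flowers, and the higher ones from 2 to 12, 9 to 52 and 0 to 7. Genes called in both genotypes went the same way in 5087, 6622 and 4218 cases and opposite ways in 3, 1 and 1, where independent lists would share 1076, 1400 and 693. In leaves the count of interaction calls was 0 without mutant control replicates 2 or 3, 23 (2 higher and 21 lower) without heated mutant replicate 2, 3 without heated mutant replicate 3 and 2 without wild-type control replicates 2 or 3 or heated replicate 3. With depth class as a term it was 72 in leaves (65 higher) and 118 in late flowers (all lower). MIR838 lost its call without mutant control 2 (3.25) or 3 (3.31). ER folding lost the camera call without wild-type control 3 (adjusted p = 0.84), wild-type heated 2 (0.29), mutant control 1 (0.76), 2 (0.32) or mutant heated 3 (0.49). Salicylate lost the camera call without wild-type control 3 (adjusted p = 0.11), wild-type heated 2 (0.46), mutant control 1 (0.57) or mutant heated 3 (0.49). The small HSP list lost the camera call without wild-type control 3 (adjusted p = 0.14), mutant control 2 (0.68) or mutant heated 2 (0.95). In early flowers the small HSP list lost the camera call without wild-type heated 1 (adjusted p = 0.15), mutant control 1 (0.72) or mutant heated 3 (0.22). In late flowers it lost the camera call without wild-type control 3 (adjusted p = 0.1), wild-type heated 3 (0.32) or mutant heated 1 (0.5).

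Heat responses of wild-type tissues were compared alike. Against leaves, the early-flower response was higher for BZIP60 (2.72 ± 0.33), BZIP28 (1.97 ± 0.36), BIP3 (4.06 ± 1.01) and ERDJ3A (2.99 ± 0.66) (n = 3 per group). It was higher for HSP101 (5.49 ± 1.46), ROF2 (6.25 ± 0.94), RD29A (5.84 ± 1.00) and ICS1 (4.35 ± 1.23). It was lower for KNOLLE (-4.60 ± 0.73), GRP17 (-8.52 ± 1.91) and DMC1 (-2.19 ± 0.58). Early-flower BIP3 went from 0.147 to 1.07 CPM, leaf BIP3 from 121 to 41.9. In all, 1580 genes had a higher and 1784 a lower response (1790 and 1671 with RLE size factors). Larger heat shock proteins had 10 higher of 23, list alone 12 (camera adjusted p = 4.7e-06, adjusted p = 0.6 with an estimated correlation), heat shock factors 8 higher of 24, list alone 10 (camera adjusted p = 1.1e-05, adjusted p = 0.21 with an estimated correlation), dehydration genes 9 higher and 0 lower of 17, list alone 13 and 1 (camera adjusted p = 2.9e-06, adjusted p = 0.47 with an estimated correlation) and salicylate genes 5 higher of 17, list alone 7 (camera adjusted p = 9.1e-06, adjusted p = 0.52 with an estimated correlation). Cell cycle genes had 10 lower of 30, list alone 16 (camera adjusted p = 2.9e-06, adjusted p = 0.6 with an estimated correlation), ER folding 3 higher and 1 lower of 25, list alone the same (camera adjusted p = 0.18), the ERAD list 4 higher of 18, list alone 5 (camera adjusted p = 0.0042, adjusted p = 0.52 with an estimated correlation) and regulators of the unfolded protein response 4 higher and 0 lower of 10, list alone 4 and 1 (camera adjusted p = 0.18). Leaf counts behind cell cycle values were low: CDKB1;1 had 1 count over the 3 leaf controls and 2944 over those of early flowers. KNOLLE went from 0.925 to 7.33 CPM in leaves, where bud transcripts were higher after heat too. Leaf controls had 88.8 to 325 CPM of HSP101, early-flower ones 24.9 to 33.3. Without wild-type replicate 1 libraries 1320 genes were called against 3364, and without a filter 33.6% of calls were higher against 47%. BIP3 lost its call without early-flower heated 1 (3.11), and GRP17 without early-flower control 2 (-4.46).

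For late flowers against leaves the response was higher for BZIP60 (2.65 ± 0.33), BZIP28 (1.71 ± 0.36), BIP3 (4.87 ± 0.81), DER1 (1.91 ± 0.32), HSP90.1 (6.27 ± 1.34) and the defence regulator gene WRKY18 (3.72 ± 0.70) (n = 3 per group). It was lower for the cold-induced gene KIN1 (-3.76 ± 0.77) and the pollen tube kinase gene BUPS1 (-2.78 ± 0.52). In all, 1138 were higher and 632 lower. Larger heat shock proteins had 7 higher of 23, list alone 15 (camera adjusted p = 9.7e-07, adjusted p = 0.5 with an estimated correlation), heat shock factors 4 higher of 24, list alone 9 (camera adjusted p = 0.0016, adjusted p = 0.5 with an estimated correlation), salicylate genes 3 higher of 17, list alone 6 (camera adjusted p = 9.1e-05, adjusted p = 0.5 with an estimated correlation) and cell cycle genes 9 lower of 30, list alone 13 (camera adjusted p = 2.2e-08, adjusted p = 0.5 with an estimated correlation). ER folding had 1 higher of 25, list alone the same (camera adjusted p = 0.12), the ERAD list 4 higher of 18, list alone the same (camera adjusted p = 0.015, adjusted p = 0.5 with an estimated correlation) and tapetum genes 1 lower of 24, list alone the same (camera adjusted p = 0.00016, adjusted p = 0.5 with an estimated correlation). The share of 64.3% higher was 50.2% (801 and 795) with RLE size factors and 31.4% without a filter. Without wild-type replicate 1 libraries 313 genes were called against 1770, and single left-out libraries gave 925 (heated late-flower replicate 2), 956 (heated late-flower 1), 942, 1069 and 1021 (late-flower controls 2, 1 and 3) and 965 and 1119 (leaf controls 2 and 3). ERAD lost the camera call without late-flower control 1 (adjusted p = 0.055), leaf control 3 (0.051) or leaf heated 2 (0.067).

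Late against early flowers gave 11 calls. Responses were higher in late flowers for 4 genes including SLD2 (3.22 ± 0.53), PIT1 (4.81 ± 0.81) and AT1G15385 (5.83 ± 0.98), and lower for 7 genes including CHX14 (-4.76 ± 0.69) and TET15 (-3.88 ± 0.70) (n = 3 per group). PIT1, AT1G15385 and CHX14 were chosen after their values were seen, and each had only 2 or 3 counts over an early-flower group (3, 2 and 3). Dehydration genes had 0 higher and 0 lower of 17, list alone 0 and 5 (camera adjusted p = 7.7e-13, adjusted p = 0.11 with an estimated correlation), and neither BZIP60 (-0.07 ± 0.33) nor BZIP28 (-0.27 ± 0.36) was called. With RLE size factors 4 were higher and 14 lower, 22.2% higher against 36.4%. DESeq2 called 86, a fit of the compared groups 57, a replicate block 22, that block in the compared groups 175, voom weights 1314 (1010 higher, 304 lower), and 0 were called without wild-type replicate 1 libraries. Single left-out libraries gave 1 (heated early-flower replicate 2), 7 (early-flower control 2), 6 (early-flower control 3) and 7 (heated late-flower 2). AT1G15385 lost its call without early-flower heated 2 (6.05) or 3 (5.89), and PIT1 without early-flower heated 2 (5.54) or 3 (4.52). SLD2 lost its call without early-flower heated 2 (3.15), and TET15 without early-flower control 2 (-3.76), early-flower heated 1 (-3.41), 2 (-4.04) or late-flower heated 2 (-3.63).

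Tissues of the wild type at 22 C give the background of these lists. Early flowers against leaves had 1920-fold (95% counting interval 344 to 75700) more of the mitotic kinase transcript CDKB1;1, 1190-fold (95% counting interval 329 to 9820) more of the meristem transcript LFY, and less of the defence genes PR1 (-12.18 ± 1.38) and PR2 (-10.48 ± 1.23) and of Rubisco activase RCA (-3.80 ± 0.48) (n = 3 per group). BZIP60 (-3.16 ± 0.25), BZIP28 (-1.63 ± 0.26) and BIP3 (-9.57 ± 0.81) were lower. Of tested genes 7155 were higher and 7258 lower (7781 and 6619 without a filter). Cell cycle genes had 30 higher of 30, list alone the same (camera adjusted p = 7e-13, adjusted p = 0.39 with an estimated correlation), floral identity genes 13 higher of 16, list alone 14 (camera adjusted p = 1.4e-06, adjusted p = 0.39 with an estimated correlation), meiotic genes 9 higher of 9, list alone the same (camera adjusted p = 0.00056, adjusted p = 0.3 with an estimated correlation) and ER folding 13 lower of 25, list alone 12 (camera adjusted p = 0.01, adjusted p = 0.62 with an estimated correlation). Late flowers against leaves had 5850-fold (95% counting interval 2000 to 28400) more of the pollen wall transcript A6, and less BZIP60 (-2.96 ± 0.25) and BIP3 (-7.16 ± 0.69), among 7632 higher and 7078 lower genes. Tapetum genes had 23 higher and 1 lower of 24, list alone the same (camera adjusted p = 1.6e-08, adjusted p = 0.19 with an estimated correlation), late pollen and sperm 29 higher and 1 lower of 31, list alone the same (camera adjusted p = 5.7e-11, adjusted p = 0.09 with an estimated correlation) and ER folding 9 lower of 25, list alone the same (camera adjusted p = 0.032, adjusted p = 0.57 with an estimated correlation). The median of all genes moved by 0.14 log2 with RLE size factors. ER folding lost the camera call without leaf control 3 (adjusted p = 0.1).

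Late against early flowers at 22 C had more of the pollen genes PPME1 (10.02 ± 0.71) and PRF4, the latter 1070-fold (95% counting interval 297 to 8870), of the ovule gene STK (5.77 ± 1.05) and of the tapetum gene MS1 (7.86 ± 1.29), and less LFY (-5.25 ± 0.65) and KNOLLE (-1.63 ± 0.45) (n = 3 per group). Late pollen and sperm had 27 higher of 31, list alone the same (camera adjusted p = 2.3e-22, adjusted p = 0.0031 with an estimated correlation), tapetum 19 higher and 1 lower of 24, list alone the same (camera adjusted p = 1.8e-06, adjusted p = 0.38 with an estimated correlation) and cell cycle 8 lower of 30, list alone 15 (camera adjusted p = 0.00068, adjusted p = 0.87 with an estimated correlation). Of tested genes 4393 were higher and 3711 lower, 54.2% higher, against 67.7% (4833 and 2310) with RLE size factors, and voom weights called 13938 (6396 and 7542) and a replicate block in the compared groups 12410 in all against 8104. In the 3 tissue pairs groups did not overlap for 13849, 14207 and 7986 called genes and for 68.1, 71.3 and 63.3% of all.

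Camera called 2 to 10 of the 18 lists per contrast, of which a selection is given. Calls that held with an estimated correlation were heat shock factors and clock genes in wild-type early flowers, small heat shock proteins, heat shock factors, dehydration and clock genes in mutant early flowers, small heat shock proteins and heat shock factors in mutant late flowers, and late pollen and sperm genes between flower stages. Of 378 list tests, median and camera direction differed in sign in 37. The camera test was called in 3 of these, all in leaves. In 59 list medians a member had 0 counts in a group, and 31 of these differed with the 3-count floor, though none of the 6 ER folding ones. Such floors cover counting error only. Within groups, the first component of residuals held 21.1% and set replicate 1 apart (54.4 to 85.6 in the shallow wild-type libraries, 3.28 to 28 in the mutant), while replicates 2 and 3 were each below 0 in 11 of 12 groups.

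**Figure D4:**
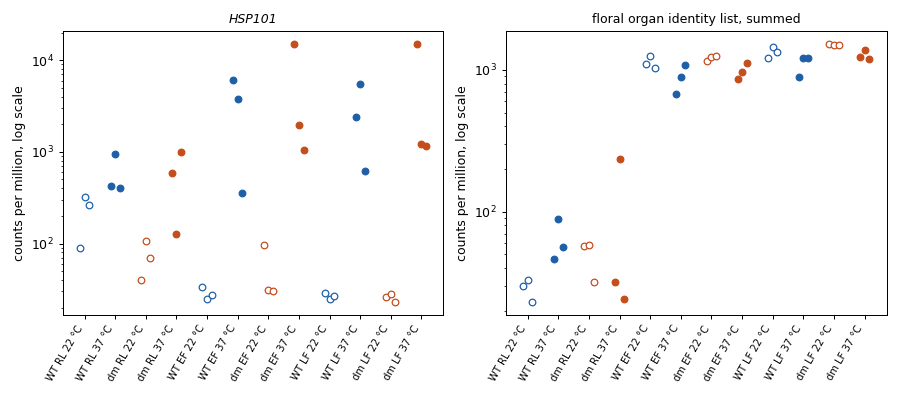
HSP101 and the summed floral organ identity list in each library, in CPM on a log scale, with open points at 22 C, filled points at 37 C, wild type in blue and double mutant in orange, n = 3 per group.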

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

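All tests here were chosen after the results were seen, except the interaction contrasts, the first bud tissue test and 2 tests of shallow groups. 4 results stood out by a test of the difference between effects. The leaf heat response differed between genotypes for 1 gene, MIR838 (3.55 ± 0.56). Between wild-type tissues the response differed for 3364 genes (early flowers against leaves), 1770 (late flowers against leaves) and 11 (late against early flowers). MIR838 was low (mutant leaves 0.18 to 1.08 CPM with heat, wild type 2.02 to 1.03).

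Libraries were regrouped within each temperature (100 splits of 200) after the tissue or genotype difference had been removed in the model. For the leaf genotype by heat interaction 79 splits called as many genes (real 1, highest other 2696), so chance was not excluded. In early and late flowers the real count was 0, so all 100 splits reach it (highest other 162 and 11) and nothing is decided. For tissues, whose libraries the replicate numbers pair, 32 splits part every pair. Only 1, the real one, called as many for early (3364, highest other 623) and late flowers (1770, 7) against leaves. The same held for late against early flowers (11, 1). Over all 100 splits, most of which leave pairs together, 1, 1 and 5 called as many (highest others 1221, 268 and 342). Chance was excluded only for flowers against leaves. Splits far above the real count, as in leaves between genotypes and between flower stages, point to a structure of the samples. Of 60 free splits without that removal, which can set tissue against tissue, 9, 7 and 13 called as many for tissues (highest other 12738, 12926 and 6395) and 55 for the leaf genotypes (2450). Of 60 that mix tissues or genotypes alike, which adds their difference to the spread, 1, 1 and 9 (411, 219 and 261) and 50 (5100) did. Neither scheme decides for tissues.

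Bud transcripts were high in heated mutant leaf replicate 2, with 25.5 CPM of AP3, 28.3 of SEP2, 20.2 of AP1 and 35.4 of PI, and a floral list sum of 237 against 24.2 to 88.7 in the other leaf libraries. The tables argue against floral genes switched on by heat throughout mutant leaves, since 0 of the 2 other heated mutant leaf libraries lay above the controls. In wild-type leaves, however, all 3 heated libraries (46.5, 88.7 and 56.6) lay above the 3 controls (29.7, 32.9 and 23). A wholly mislabelled bud sample is also argued against, since the sum was 27.4% of the lowest heated mutant bud library, although an earlier form of that test on photosynthesis genes came out as a mislabelled sample would (-0.467 log2) but separated nothing, with 3 leaf libraries at or below the highest bud library. Bud tissue or RNA in that library stays open: 66.7% (2 of 3 genes) in the first form of the test were above all other leaf libraries, too few to tell, and 2 other leaf libraries gave 100 and 75% in that form. Of 4 later forms with other gene limits, which gave 0, 20, 70.6 and 92.2%, the last gives the highest share (47 of 51 genes, at a median of 14.4% of the bud level). With that library set aside, the same form gave 60% (33 of 55 genes) at a median of 2.95% for heated wild-type leaf replicate 3, and 0 to 20.8% at medians of 0.0954 to 1.77% for the other 10. These values go with bud tissue, but choosing among forms after seeing them may favour it.

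The 2 shallow mutant groups, leaf controls and heated late flowers, shared calls such as lower MIR838 (-3.52 ± 0.45 and -2.79 ± 0.45). A broad batch shared by them stays open: their differences from wild type correlated at 0.344 across 16331 genes (not independent replicates), against 0.38, 0.318 and 0.314 for the other 3 pairs of leaf and late-flower groups. The bound set beforehand (at or below the highest) was met, but by no more than their SD (0.037), and the pair at 0.38 shares a shallow group. Shallow sequencing by itself stays open. Its test was a correlation of -0.48 across genes with replicate 1 minus replicates 2 and 3 in 4 other wild-type groups. It decides nothing, since wild-type replicate 1 libraries deviate together and are part of the subtracted mean. With depth class as a term MIR838 was still called (-3.21 and -2.50), but only those libraries inform it. In the other genotype comparisons MIR838 was at -0.27 to 0.19. For such single genes a batch stays open, and no biological explanation was tested.

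The strength of the heat response differed among replicates, with 14900, 1970 and 1060 CPM of HSP101 in heated mutant early flowers. Depth class is argued against, since these 3 libraries were all deep and differed 14.1-fold. A difference present without heat stays open: replicate 1 was highest in 2 of 6 control groups by the median of the larger heat shock proteins (3 by HSP101), but those 2 were mutant early flowers (HSP101 96.3, 31.4 and 30.7 CPM) and late flowers, where heated replicate 1 was highest too, and only the number ties a control to a heated library. A run or day marked by the replicate number cannot be told apart from chance: replicate 1 was highest in 4 of 6 heated groups by that median (3 by HSP101), and no label says what the number stands for.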

How the results depend on the processing

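Depth class as a term, the fit without wild-type replicate 1 libraries and limma voom with library weights were chosen after the data were seen. Values are counts of called genes that lay more than 1.5 times from the main count, by setting. Main counts were: wild-type heat (early flowers 8344, late flowers 5924, leaves 7355), mutant heat (early flowers 7613, late flowers 5044, leaves 6622), genotypes at 22 C (early flowers 29, late flowers 6, leaves 18), genotypes at 37 C (early flowers 4, late flowers 7, leaves 16), genotype by heat (early flowers 0, late flowers 0, leaves 1), tissue by heat (early flowers and leaves 3364, late and early flowers 11, late flowers and leaves 1770), tissues at 22 C (late and early flowers 8104), weaker induction in the mutant (early flowers 0, late flowers 0, leaves 0), heat calls shared by 3 wild-type tissues (higher 1422, lower 757). With the DESeq2 Wald test: genotypes at 22 C (early flowers 108, late flowers 21, leaves 115), genotypes at 37 C (early flowers 33, late flowers 23, leaves 114), genotype by heat (early flowers 12, late flowers 3, leaves 25), tissue by heat (late and early flowers 86), weaker induction in the mutant (early flowers 2, late flowers 1, leaves 12), heat calls shared by 3 wild-type tissues (lower 1170). With limma voom with library weights: wild-type heat (early flowers 13154, late flowers 11173), mutant heat (early flowers 14859, late flowers 10581), genotypes at 22 C (early flowers 63, late flowers 190, leaves 119), genotypes at 37 C (early flowers 1858, late flowers 114, leaves 9), genotype by heat (early flowers 21, late flowers 3, leaves 2), tissue by heat (early flowers and leaves 5448, late and early flowers 1314, late flowers and leaves 3766), tissues at 22 C (late and early flowers 13938), weaker induction in the mutant (early flowers 4, late flowers 1), heat calls shared by 3 wild-type tissues (lower 1431). With depth class as a term: genotypes at 22 C (leaves 440), genotypes at 37 C (late flowers 437), genotype by heat (late flowers 118, leaves 72), tissue by heat (late and early flowers 18), weaker induction in the mutant (late flowers 7, leaves 1 with 5 stronger). With libraries of the compared groups only: wild-type heat (leaves 4896), mutant heat (late flowers 8081, leaves 402), genotypes at 22 C (early flowers 6, leaves 0), genotypes at 37 C (early flowers 0, late flowers 3, leaves 0), genotype by heat (leaves 0), tissue by heat (late and early flowers 57). With libraries of the tissue only: wild-type heat (late flowers 9672, leaves 3672), mutant heat (late flowers 8807, leaves 3214), genotypes at 22 C (early flowers 2, leaves 4), genotypes at 37 C (leaves 2), genotype by heat (leaves 0). With a replicate block: genotypes at 22 C (early flowers 56, late flowers 19), genotypes at 37 C (early flowers 19, late flowers 11, leaves 33), tissue by heat (late and early flowers 22). With a replicate block in the compared groups only: wild-type heat (late flowers 9240, leaves 4541), mutant heat (leaves 1080), genotypes at 22 C (early flowers 4, leaves 0), genotypes at 37 C (early flowers 0, late flowers 3, leaves 0), genotype by heat (leaves 0), tissue by heat (late and early flowers 175), tissues at 22 C (late and early flowers 12410). With wild-type replicate 1 libraries left out: wild-type heat (early flowers 5328, late flowers 2737), genotypes at 22 C (early flowers 56), genotypes at 37 C (leaves 10), tissue by heat (early flowers and leaves 1320, late and early flowers 0, late flowers and leaves 313), heat calls shared by 3 wild-type tissues (higher 764, lower 187). With log2 changes of at least 1 in size: heat calls shared by 3 wild-type tissues (higher 592, lower 437). With RLE size factors: tissue by heat (late and early flowers 18). The cause of these differences was not tested.

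With each library left out in turn, where a group of 2 is assumed to vary like the others, counts ran over these ranges: wild-type heat (early flowers 6424 to 7501, late flowers 4042 to 5593, leaves 5923 to 6781), mutant heat (early flowers 5153 to 8167, late flowers 3060 to 4252, leaves 5494 to 7116), genotypes at 22 C (early flowers 2 to 96, late flowers 2 to 10, leaves 15 to 138), genotypes at 37 C (early flowers 4 to 5, late flowers 6 to 8, leaves 8 to 224), genotype by heat (early flowers 0 to 0, late flowers 0 to 0, leaves 0 to 23), tissue by heat (early flowers and leaves 2495 to 3595, late and early flowers 1 to 16, late flowers and leaves 925 to 1963), tissues at 22 C (early flowers and leaves 13417 to 13922, late and early flowers 5681 to 6414, late flowers and leaves 13532 to 14441), weaker induction in the mutant (early flowers 0 to 0, late flowers 0 to 0, leaves 0 to 20). In mutant leaf heat, AP1 (3.61), AP3 (2.99) and STK (4.55) turned to -2.71, -3.65 and -4.62 without heated replicate 2, AP1 and AP3 to -1.48 and -2.87 with library weights, and AP3 to -0.02 with a block in the compared groups. Over left-out libraries AP1 ran from -2.71 to 4.94, AP3 from -3.65 to 3.58 and STK from -4.62 to 9.20. Camera directions turned with 1 library left out for salicylate between genotypes at 22 C (adjusted p = 0.23 without mutant control 1, range 2e-10 to 0.23), small heat shock proteins between genotypes at 22 C (adjusted p = 0.72 without mutant control 2, range 1e-06 to 0.72), ER folding in genotype by heat (adjusted p = 0.29 without heated wild type 2 and 0.76 without mutant control 1, range 7.3e-06 to 0.84), salicylate in genotype by heat (adjusted p = 0.57 without mutant control 1, range 1.4e-09 to 0.57), all in leaves. The cause was not tested. No filter, the stricter filter and removal of organelle-encoded genes left every count of called genes within 1.5 times of the main one, but each turned the direction with more calls in wild-type leaf heat, late-flower heat of both genotypes, tissue by heat of late flowers and leaves, and early flowers and leaves at 22 C, as the 2 filter settings did in mutant leaf heat and fits of the tissue or the compared groups in early-flower heat of both genotypes. Of 3923 refits of 210 named-gene values, 3635 kept their side of the threshold, whatever the sign of uncalled ones. In 270 a call was lost, in 12 gained and 6 called values turned. For 2092 refits of 110 list tests these were 1855, 177, 55 and 5. Depth limits what is seen of low genes: mutant leaf controls and heated mutant late flowers held 11.3 to 13.5 M counts a library, and depth class there goes with treatment.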

Other observations

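The splits in this part were chosen after the results were seen, unlike the genotype contrasts and the replicate blocks. The 6 libraries of a 2-group comparison allow only 10 splits of 3 against 3, too few for a share under 0.05. The number of splits calling as many genes is given first, the real one included, then the real count and the highest other. For wild-type heat these were 1, 7355 and 660 in leaves, 1, 8344 and 154 in early flowers and 1, 5924 and 5 in late flowers. For mutant heat they were 1, 6622 and 4526, then 1, 7613 and 268, then 1, 5044 and 0. Between genotypes at 22 C they were 8, 18 and 2851 in leaves, 2, 29 and 49 in early flowers and 1, 6 and 0 in late flowers, and at 37 C 8, 16 and 2056, then 3, 4 and 1969, then 2, 7 and 187. Between tissues they were 1, 14413 and 15 (early flowers against leaves), 1, 14710 and 4 (late flowers against leaves) and 1, 8104 and 3 (late against early flowers). Splits calling many times the real count, as between genotypes in leaves and in heated flowers, point to a structure of the samples. At 37 C the highest split in each tissue set mutant replicate 1 and wild-type replicates 1 and 2 against the rest. With replicate number as a block the genotype calls at 37 C were 33, 19 and 11 against 16, 4 and 7, but 0, 0 and 3 with that block in the compared groups only.

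AT1G43000 starts 3062 bases beyond the end of BZIP60 on chromosome 1 (bases 16140526 to 16141792) and was singled out after its values were seen. It was higher in mutant leaves at 22 C (2.63 ± 0.55). AT1G43000 lost its call without wild-type control 1 (2.31), 2 (2.52) or mutant control 3 (1.1). AT4G01980 was higher in the mutant in all 6 comparisons between genotypes (2.38, 6 and 4.03 at 22 C, 2.75, 6.48 and 3.88 at 37 C). QQS was called higher in 4 of the 6, with all 6 values above 0.

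Replicate numbers paired the libraries in 10 of 21 contrasts (r of 0.1 to 0.62 across genes, which are not independent replicates), and 30 of 36 libraries correlated best with libraries of their own number.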
